A study of Mus musculus with 18 samples.

How the data were processed

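Bulk RNA of CD8+ T cells, CD4+ T helper cells and dendritic cells, sorted from MC38 tumours of mice given anti-PD-1, alone or together with D18, was measured in 18 libraries, 3 per treatment and cell type. Per the labels, cells were sorted into lysis buffer and total RNA was turned into Smart-Seq2 libraries, which keep no strand and carry no molecular identifiers. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.4.0, counted per gene with HTSeq 0.6.1 and normalised by the authors with DESeq2, whose version is not given in the sources used here. Samples were grouped by the sort, treatment and replicate number in the labels, and all 18 were used.

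The deposited tables, 1 per cell type with 46983 genes and 6 libraries each, hold log2 values made by the authors with a variance-stabilising transform of reads divided by a size factor per library. The labels do not say which transform. A gene without a read sits at the minimum of its table (2.17 for CD8+ T cells, 1.34 for CD4+ T cells, 2.22 for dendritic cells). Undoing the transform and dividing by the smallest value above 0 in each library gave whole numbers for 100% of the values, within a tolerance of 0.001. The size factors implied by these reads equalled median-ratio size factors over the genes with reads in all 6 libraries (3606, 2086 and 1414 genes), with a largest relative difference of 1.8e-14. The recovered reads per library run from 11170 to 266392, and a count of 0 leaves an upper limit of 3 reads at 95% confidence. Symbols and mm10 places were found for 46488 gene IDs (98.9%).

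Changes were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend and robust settings) on log2(normalised reads + 1), where normalised reads are recovered reads divided by the size factor. Genes with a mean of at least 10 over the 6 libraries of a cell type were tested, without a block, and the Benjamini-Hochberg adjusted p was held against 0.05. Every adjusted p of a gene or list comes from limma and its functions camera and fry, with 3 libraries per group. Interactions were tested as a limma contrast over all 18 libraries after each library had been centred within its cell type, in genes with a mean of at least 10 in both cell types. Gene lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a cell type, and again with an estimated correlation and with fry. CPM were taken over the recovered reads of a library. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

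The tests, the gene lists, the rule for named genes and the alternatives called planned were chosen before the data were examined. The rule names, per cell type and direction, the 12 genes with the largest change among those that pass with groups that do not overlap. Where none passes, it names the 6 with the smallest unadjusted p at a mean of at least 50 in the higher group, which was the case in all 3 cell types. It adds up to 4 members per biology list, a set of immune genes given whatever their result, and the 5 genes with the smallest p of each interaction. A pair of genes that the rule names is not reported here. Members of the lists of other cells named in the text, and genes that passed only under an alternative, were chosen after their values were seen. Pairing by replicate number was planned as an alternative, and whether libraries of the same number deviate together was checked by correlating deviations from group means. The batch of a library was read from its reads of mt-Co2, mt-Co3 and mt-Atp6 after the data had been examined, and a limma model with batch as a term gives the within-batch changes.

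Alternatives tried were quantile normalisation, limma-voom with quality weights on the recovered reads, no filter, a mean of at least 100, pseudocounts of 0.1 and 10, the replicate block, 1 fit of all 18 libraries, a limit of 1 on the absolute log2 change, and each library left out in turn. Added after the data had been examined were the deposited log2 values as they stand, omission of both libraries numbered 3, of libraries over 50% mitochondrial or under 20000 reads and of the pair with at most 1 Cd3e read, the batch term, a macrophage score as covariate, and variants of the block. The test was tested on simulated data by raising or lowering genes in the recovered values under the 9 other splits of each cell type. In each split 200 of 1569, 966 or 886 genes were changed, at folds from 2 to 16, so the shares called hold for that many changed genes. At 4-fold 32.4% of the changed genes were called in CD8+ T cells, 23.3% in CD4+ T cells and 2.89% in dendritic cells, and at 16-fold 84.7%, 76.2% and 62.9%. In counts simulated with the dispersion estimated by level, 70%, 54% and 64% of genes changed 4-fold were called, and with a dispersion of 0.05 98%, 98% and 94%. The negative-binomial count test planned for recovered reads was not run, since the deposited unit is log2, and limma-voom on those reads took its place. Raw reads were not analysed here, and no untreated tumour is among the samples.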

Results

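RNA was sequenced from immune cells sorted out of subcutaneous MC38 tumours, which grow from a mouse colon carcinoma line in C57BL/6 mice. The mice received anti-PD-1, an antibody against the inhibitory receptor encoded by Pdcd1, or the same antibody plus D18, an agent known here only by its code name. Per the labels' protocols, treatment of 6-week-old females began at a mean tumour volume of 100 mm3 and ran for 2 weeks, with 200 µg of anti-PD-1 per mouse given 2 times per week and 25 µg of D18 per mouse given 1 time per week. CD8+ T cells, CD4+ T helper cells and dendritic cells were sorted, and each of the 3 sorts gave 3 libraries with anti-PD-1 and 3 with anti-PD-1 plus D18 (below, D18), 18 in all. No untreated tumour was included, so every comparison asks what D18 added to PD-1 blockade. The mice were pooled before they were divided, and no source says that replicates came from separate mice, so the p-values measure the spread between these samples, whatever its source.

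The libraries were shallow and uneven. In the CD8+ T cell sort, the anti-PD-1 libraries held 78210, 189711 and 143466 reads assigned to genes and the D18 libraries 55823, 266392 and 77993. In the CD4+ T cell sort the totals were 151689, 144281 and 118730 with anti-PD-1 and 59505, 31156 and 137295 with D18. In the dendritic cell sort they were 59479, 222402 and 171025 with anti-PD-1 and 190641, 11170 and 169296 with D18. A library held reads of 4292 to 11973 genes. A count of 0 allows up to 3 reads, which is 11.3 CPM in the deepest library and 269 CPM in the shallowest. Smart-Seq2 reads carry no molecular identifiers, so these floors cover counting error only. Transcripts of all mitochondrial genes, ribosomal RNA included, took 2.39% of the reads in dendritic cell anti-PD-1 replicate 1 and 71.9% in replicate 2 of the same group. In the CD4+ T cell sort they took 40.1%, 67.7% and 21.8% with anti-PD-1 and 26.2%, 2.85% and 22.1% with D18.

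Marker genes separated the sorts in only part of the libraries. Cd3e, a subunit of the T cell receptor complex, had 0 and 1 reads in CD4+ T cell anti-PD-1 replicates 1 and 2 and 45 in replicate 3, against 23, 10 and 41 with D18. The same first pair of libraries held 304 and 677 reads of H2-Aa, an MHC class II gene of antigen-presenting cells, against 10 and 16 in D18 replicates 1 and 2, while the libraries numbered 3 held 160 with anti-PD-1 and 241 with D18. CD4+ T cell D18 replicate 3 held 83 reads of Cd8a and 2 of Cd4. In the dendritic cell sort, genes of the T cell list held 0, 1 and 557 reads with anti-PD-1 and 35, 6 and 1063 with D18, so both libraries numbered 3 stood apart. Those numbered 3 in the CD8+ T cell sort stood apart too, with 2858 (anti-PD-1) and 4308 (D18) CPM of the T cell list, against 8835 to 15049 CPM in the other 4, and with 342 and 120 reads of H2-Aa beside 45 and 28 of Cd8a. D18 replicate 2 of that sort held 349 reads of H2-Aa beside 585 of Cd8a. Whether samples were mixed or exchanged is not given in the sources used here, and the changes between treatments carry that doubt. Lyz2, a gene of macrophages and other myeloid cells, had reads in all 18 libraries, from 11 in CD8+ T cell D18 replicate 1 to 2068 in dendritic cell D18 replicate 1. In the dendritic cell sort the monocyte and macrophage list took 51985, 22154 and 40000 CPM with anti-PD-1 and 32973, 14145 and 29416 CPM with D18. The dendritic cell list took 12542, 12545 and 7356 CPM against 9437, 4118 and 6858 CPM. Changes in that sort may therefore come from macrophages.

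**Figure D1:**
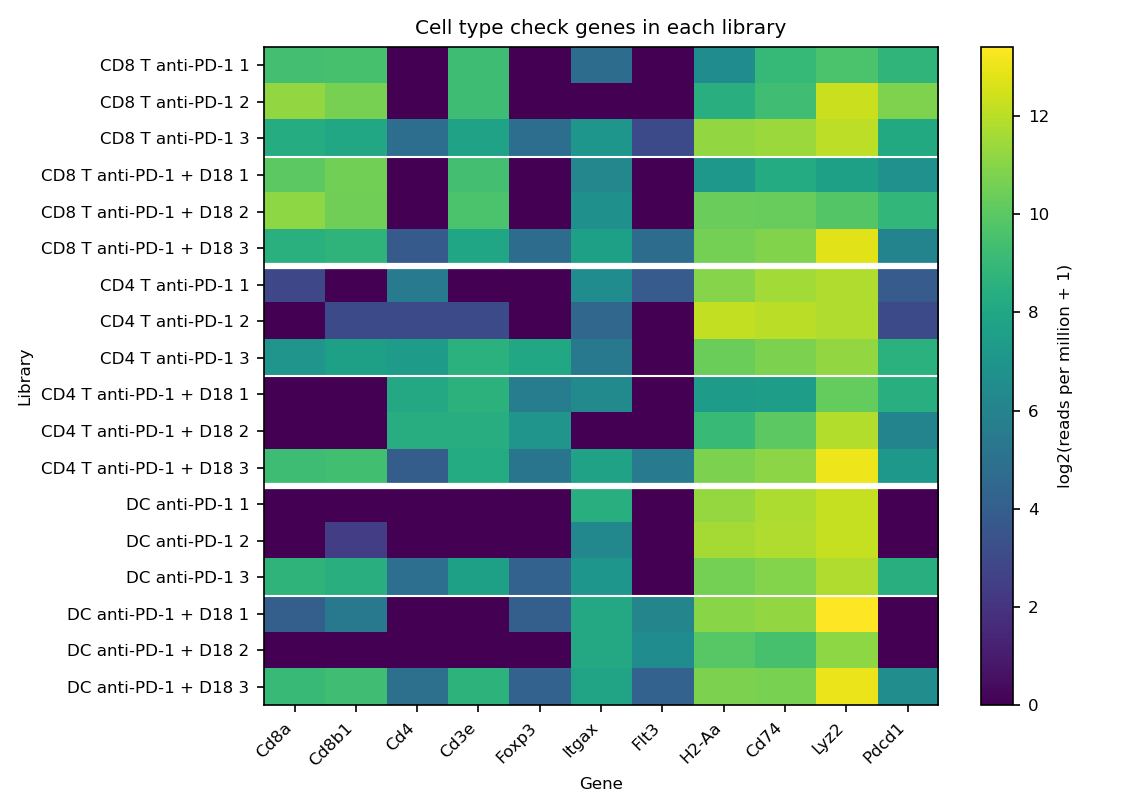
Colour gives log2(CPM + 1) of 11 genes that mark the sorted cell types, in each of the 18 libraries (lines part the sorts and the treatments). Cd3e had 0 and 1 reads in CD4+ T cell anti-PD-1 replicates 1 and 2, and in the dendritic cell sort it had 34 and 69 reads in the libraries numbered 3.

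The libraries also fell into a pair of sets that cross the treatments unevenly, called batches here although no label names a batch. The mitochondrial genes mt-Co2, mt-Co3 and mt-Atp6 had 0 reads in anti-PD-1 replicates 1 and 2 of all 3 sorts, 6 libraries in which mt-Cytb had between 115 and 64685 reads. In the other 12 libraries, which are anti-PD-1 replicate 3 of each sort and the 9 D18 libraries, the 3 genes together had between 5 and 334 reads. Pseudogenes took 0.231% to 0.507% of the nuclear reads in the 6 libraries and 0.694% to 3.62% in the 12. Only 1 anti-PD-1 library per sort shares a batch with the D18 libraries. The change within that batch, from a model with batch as a term, therefore rests on that library, taken to vary like the others. It is given for part of the genes and lists. In the CD4+ T cell sort, anti-PD-1 replicates 1 and 2 are also the libraries with 0 and 1 reads of Cd3e. The batch term there cannot be told from cell content.

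**Figure D2:**
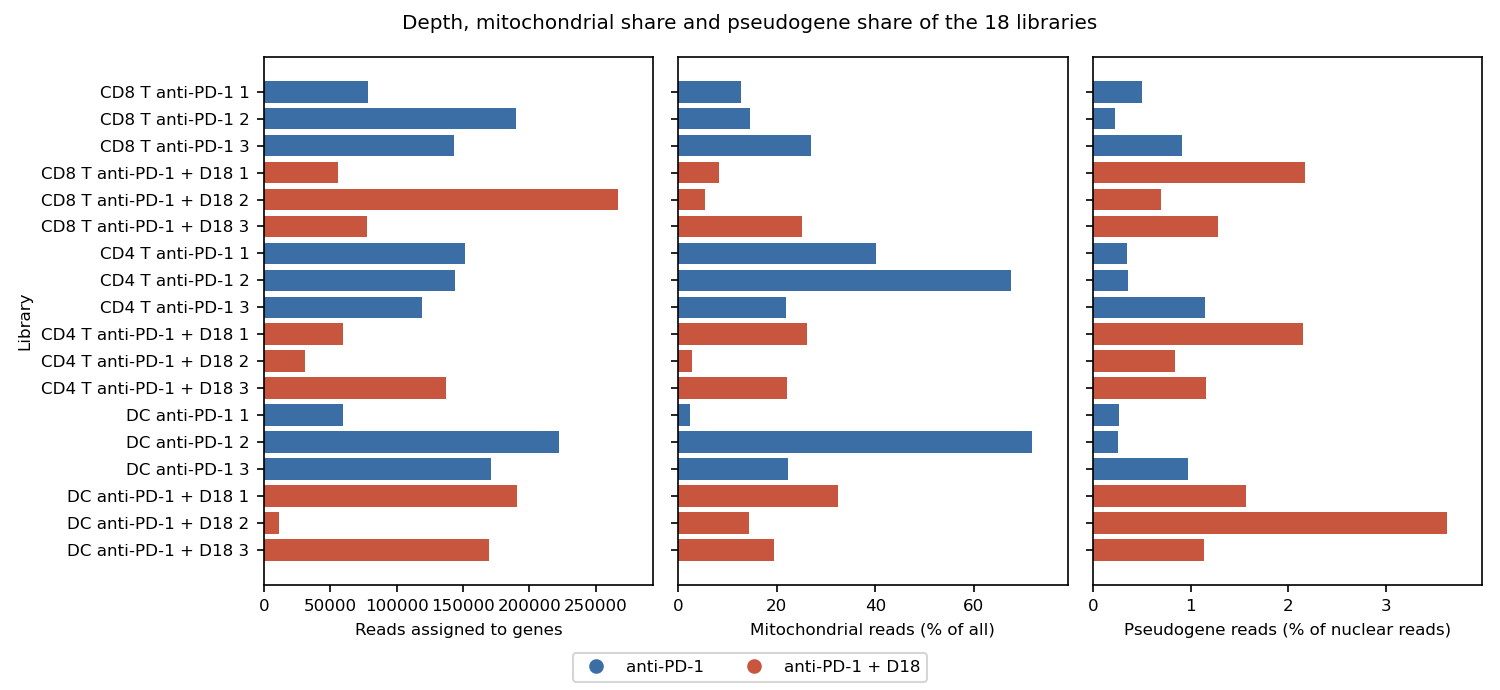
Bars give, for each of the 18 libraries, the reads assigned to genes, the percent of them from mitochondrially encoded genes and the percent of nuclear reads from pseudogenes (blue, anti-PD-1; red, anti-PD-1 plus D18). The lowest pseudogene shares, 0.231% to 0.507%, belong to anti-PD-1 replicates 1 and 2 of the 3 sorts.

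In the CD8+ T cell sort, Gzma, which encodes a granzyme that cytotoxic lymphocytes release into target cells, had 0 reads in each of the 3 anti-PD-1 libraries and 17, 350 and 28 reads with D18. Against a floor of 3 reads over the anti-PD-1 group, the pooled D18 reads are at least 116-fold higher, and at least 47.6-fold without D18 replicate 2. These limits cover counting error only, not the spread between libraries. The tested log2 change, a difference of group means held down by the pseudocount of 1, was 5.85 ± 1.04 (SE, n = 3 per group), or 57.6-fold. Transcripts of Pdcd1, the receptor that the antibody binds, went the other way, with 34, 343 and 41 reads under anti-PD-1 and 6, 126 and 5 with D18 (−2.05 ± 0.77). Markers of monocytes and macrophages fell as a list, with a median log2 change of −2.19 and 19 of 20 tested members negative (adjusted p = 2.9e-05 by camera, but 0.745 with an estimated correlation and 0.688 by fry). Gene by gene, the unpaired limma test called 0 of 1569 genes, with a smallest adjusted p of 0.534. An unadjusted p under 0.05 was found for 130 genes (50 higher, 80 lower). limma-voom on the recovered reads also called 0, and limma on the deposited log2 values called 1, Gzma (3.88, adjusted p = 0.0499). Without D18 replicate 3, 2 genes passed, Apoe (−5.94) and the complement receptor gene C3ar1 (−5.36), each with an adjusted p of 0.0151. The groups did not overlap for 14.5% of the genes, against 10% by chance.

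Libraries with the same number deviated together in this sort (correlations of 0.36, 0.51 and 0.56 for the 3 numbers). In the CD4+ T cell sort the same correlations were −0.14, 0.15 and −0.20 and in the dendritic cell sort 0.03, −0.09 and 0.14. The block called 0 genes in both of those sorts. Within numbers 1 and 2 the block sets libraries of different batches against each other. With the replicate number as a block 20 genes passed in CD8+ T cells, 9 higher and 11 lower with D18, of 316 with an unadjusted p under 0.05. Those of the 20 that the rule for named genes did not pick were chosen after their values were seen. Gzma rose (adjusted p = 0.0141 by limma with the block, gene ENSMUSG00000023132.7, mm10 chromosome 13, 113093825 to 113100981). So did Ly6c2, a surface glycoprotein of monocytes and memory-type CD8+ T cells (1.62, adjusted p = 0.0300). Itgal, the alpha chain of the integrin LFA-1, rose by 1.66 (adjusted p = 0.0340, ENSMUSG00000030830.18, chromosome 7, 127296260 to 127335138). Ctla2a (1.78), Crip1 (2.01), S100a10 (1.41), the long noncoding RNAs AW112010 (1.56) and Malat1 (1.55), and Lars2, the mitochondrial leucyl-tRNA synthetase (2.84), rose with them. Pdcd1 fell (adjusted p = 0.0141, ENSMUSG00000026285.7, chromosome 1, 94038305 to 94052553), as did Serpina3g, an interferon-induced serine protease inhibitor (−1.57). The mitochondrial transcripts mt-Cytb (−2.51), mt-Nd5 (−1.85), mt-Co1 (−1.73) and mt-Nd1 (−1.63) fell, and so did Gpx1 (−1.63), Sat1 (−1.88) and Grn (−1.84). Cd72 (−3.14) and Fcgr2b (−2.09), inhibitory receptors of B cells and myeloid cells, were the last of the 11. With batch as a term, 0 genes passed by limma (60 with an unadjusted p under 0.05). Within the batch the change of Gzma was 5.85, of Itgal 2.44, of Pdcd1 −1.23 and of Lars2 2.12. These values rest on anti-PD-1 replicate 3, with 2858 CPM of the T cell list against 8835 to 15049 CPM in libraries numbered 1 and 2. They therefore cannot be told from a difference in cell content. The blocked count was 15 without pair 1, 28 without pair 2 and 1, Apoe (−5.67), without pair 3.

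**Figure D3:**
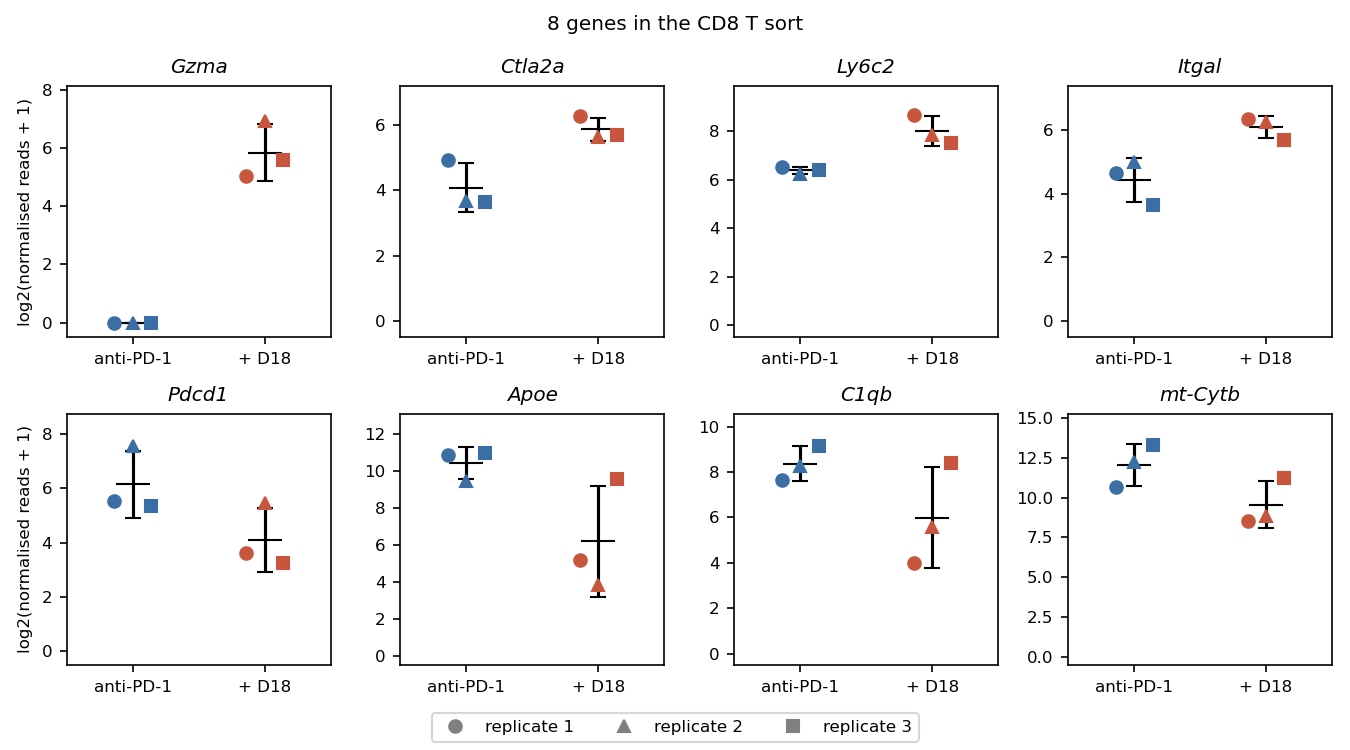
Points give log2(normalised reads + 1) of 8 genes in the 6 CD8+ T cell libraries (blue, anti-PD-1; red, anti-PD-1 plus D18; shape, replicate number), with the mean and SD of each group of 3. Gzma had 0 reads in the 3 anti-PD-1 libraries, and Pdcd1 was lower with D18 within each replicate number.

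Among the cytotoxic effector genes, 9 of 14 tested members were higher and 5 lower with D18, with a median log2 change of 0.60. The list did not pass camera (adjusted p = 0.189, and adjusted p = 0.745 with an estimated correlation). Over all genes 0 members passed, and adjusted over the list alone 1 did, Gzma. Tnf, an inflammatory cytokine, had 2, 23 and 11 reads with anti-PD-1 and 32, 39 and 17 with D18 (1.82 ± 0.69). Ifng, the effector cytokine of these cells, changed by no more than its error (0.72 ± 0.90), and its sign turned, to −0.05, without anti-PD-1 replicate 1. The granzyme gene Gzmb (0.86 ± 0.66, and 2.21 within the batch) and the pore-forming Prf1 (−1.22 ± 1.08) also had errors close to their changes. Values within the batch rest on anti-PD-1 replicate 3, which was low in T cell reads. Interferon-gamma-induced genes were higher in 12 of 14 members (median 0.62, adjusted p = 0.0577, and adjusted p = 0.745 with an estimated correlation), with Igtp at 0.98, Nlrc5 at 1.21 and Serpina3g, at −1.57, on the other side. Type I interferon-stimulated genes were lower in 10 of 16 (median −0.44, adjusted p = 0.189, and adjusted p = 0.745 with an estimated correlation), and 1, the antiviral enzyme gene Oas1a (−1.68 ± 0.36), passed adjusted over the list alone. Inhibitory receptors and exhaustion genes were lower in 7 of 10 (median −0.61, adjusted p = 0.349, and adjusted p = 0.745 with an estimated correlation), among them Lag3 (−1.14, and −0.21 within the batch). Havcr2, the exhaustion marker TIM-3, had 1, 53 and 18 reads against 4, 96 and 7 (0.50 ± 0.99, and −0.25 within the batch). Tcf7, a transcription factor of memory and stem-like T cells, had 21, 32 and 4 reads against 1, 16 and 2 (−1.68 ± 1.10, and −0.16 within the batch). The proliferation gene Mki67, with at most 13 reads in a library, was too low to test.

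The remaining lists in this sort did not pass either. Medians were 0.28 for naive, memory and stem-like genes (adjusted p = 0.610), 0.24 for activation and costimulation (0.885), 0.24 for tissue-residence and homing (0.610, its mean lying just below 0) and −0.32 for cell cycle (0.526). For metabolism they were −0.13 for glycolysis (adjusted p = 0.227), −0.12 for hypoxia response (0.567) and 0.35 for nuclear-encoded oxidative phosphorylation (0.189). The unfolded protein response (−0.24, adjusted p = 0.211), MHC class I presentation (−0.03, 0.610) and sample-handling stress genes (0.31, 0.211) complete them, and with an estimated correlation the smallest adjusted p of all these lists was 0.745. In hypoxia response 1 member passed adjusted over the list alone, the mitophagy receptor gene Bnip3 (−1.37 ± 0.39). Leaving out 1 library brought in lists that had not passed. Interferon-gamma-induced genes passed without anti-PD-1 replicate 1 (adjusted p = 0.00710) or D18 replicate 1 (0.00275). Without anti-PD-1 replicate 2, type I interferon-stimulated (adjusted p = 0.0150) and cytotoxic genes (9.0e-04) passed, and dendritic cell markers did so without anti-PD-1 replicate 3 (0.00259). Oxidative phosphorylation passed without D18 replicate 2 (adjusted p = 0.00210) and mitochondrial transcripts without D18 replicate 3 (4.6e-04). With batch as a term 7 lists passed, a comparison that rests on anti-PD-1 replicate 3, the library with 2858 CPM of the T cell list. Up were cytotoxic effector genes (adjusted p = 0.00249), interferon-gamma-induced genes (0.0194) and naive, memory and stem-like genes (0.0373). Down were macrophage markers (adjusted p = 1.0e-07), mitochondrial transcripts (6.3e-06), dendritic cell markers (0.0355) and type I interferon-stimulated genes (0.0465).

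Some transcripts of other cells were also lower with D18 in the CD8+ T cell sort, without a gene that passed the unpaired limma test of all libraries (0 called, 130 with an unadjusted p under 0.05). Apoe, a lipid carrier that tumour macrophages make in quantity, had 1391, 1268 and 2103 reads with anti-PD-1 and 19, 38 and 444 with D18 (−4.26 ± 1.35, ENSMUSG00000002985.15, chromosome 7, 19696109 to 19699188). The complement genes C1qa (−2.40), C1qb (−2.37) and C1qc (−2.01) and the lysosomal protease gene Ctsb (−2.18) lay on the same side. The list of monocyte and macrophage markers passed camera (adjusted p = 2.9e-05, and 1.0e-07 with the block), but its adjusted p with an estimated correlation was 0.745 and by fry 0.688. No omission of 1 library lost the call, the highest adjusted p being 0.00349, and within the batch the median was −3.12. Ly6c2 is the 1 member that was higher with D18. The macrophage list took 29178, 25064 and 41404 CPM with anti-PD-1 and 5410, 6795 and 26695 CPM with D18. Dendritic cell markers had a median of 0.78 (adjusted p = 0.341, and adjusted p = 0.745 with an estimated correlation), and −1.80 within the batch. Mitochondrially encoded transcripts had a median of −0.94 (adjusted p = 0.189, 0.0148 with the block, and adjusted p = 0.745 with an estimated correlation). Among them are mt-Co2, mt-Co3 and mt-Atp6, with 0 reads in anti-PD-1 replicates 1 and 2. Within the batch the median of the list was −2.26, with 10 of 10 members negative. This list and Lars2 hold sequence that occurs in near-identical copies elsewhere in the genome. The share of all mitochondrial genes, which counts ribosomal RNA outside the list, was 12.8%, 14.5% and 26.9% with anti-PD-1 against 8.34%, 5.43% and 25.1% with D18. The list alone took 47257, 89721 and 141818 CPM against 13865, 20811 and 56877 CPM.

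In the CD4+ T cell sort, the treatments differed along with the Cd3e reads given above. The T cell list took 79.1, 159 and 6519 CPM with anti-PD-1 and 7176, 7190 and 5390 CPM with D18, so replicates 3 ran the other way. Macrophage markers took 48356, 26358 and 23170 CPM against 8554, 27764 and 27889 CPM, which overlap. Ms4a4b, a membrane protein of T cells, had 1, 1 and 54 reads with anti-PD-1 and 52, 48 and 164 with D18 (log2 change 4.09 ± 1.08, SE, n = 3 per group, ENSMUSG00000056290.15, chromosome 19, 11443553 to 11467055). Icos, a costimulatory receptor of activated helper cells, had 0, 2 and 48 reads against 59, 48 and 25 (3.37 ± 1.25). Lgmn, a lysosomal protease of antigen-presenting cells, had 433, 257 and 168 against 16, 24 and 76 (−2.56 ± 0.57, ENSMUSG00000021190.14, chromosome 12, 102394084 to 102439813). Of 966 genes tested with limma, 0 passed, with a smallest adjusted p of 0.453. An unadjusted p under 0.05 was found for 100 (36 higher, 64 lower), limma-voom called 0, and the groups did not overlap for 14.5% of the genes, against 10% by chance. In anti-PD-1 replicate 3, the library of that group with T cell reads, the values of Ms4a4b and Icos lay near those with D18, and within the batch their changes were 1.26 and 0.61. Without that library 19 genes passed, 17 higher with D18 (Ms4a4b, 5.50, adjusted p = 0.00227, with the T cell adhesion gene Cd2, 4.61, and the interleukin-2 receptor gene Il2rb, 5.30) and 2 lower (Lgmn, −3.04, and Rnase4, −2.85). Without both libraries numbered 3, where batch and treatment coincide, 34 passed, 11 higher and 23 lower, the latter with the MHC class II genes H2-Aa (−4.24) and Cd74 (−3.88). Without the pair of libraries that lack Cd3e, or with batch as a term, 0 passed by limma (4 and 2 genes with an unadjusted p under 0.05). Cd2, Il2rb, Rnase4, H2-Aa and Cd74 were chosen after their values were seen.

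Other genes with the smallest p in this sort were Id2, a transcriptional regulator of effector lymphocytes (14, 19 and 77 reads against 78, 37 and 179), Actg1 (1.41), Eef2 (1.39) and Vim (1.57). On the lower side were Sat1 (−2.66), Gpx1 (−2.56), Fcgr2b (−2.57), Dusp1 (−1.77) and Snx5 (−2.13), and none of these passed. By camera 7 of 17 lists passed. Interferon-gamma-induced genes rose as a list (9 of 10 members positive, median 1.45, adjusted p = 0.00366), with Gbp2 at 2.58, Irgm1 at 1.18 and Tap1 at 1.83 (−0.30 within the batch). Activation and costimulation genes rose (9 of 10, 1.83, adjusted p = 0.00687), with Icos, Cd69 at 2.21 and Tnfrsf9 at 2.86, the last at −0.83 within the batch. Glycolysis genes rose (12 of 12, 0.84, adjusted p = 0.00687), with Pgk1 at 1.62 and Aldoa at 1.00, and so did regulatory T cell genes (6 of 6, 1.78, 0.0284), with Tnfrsf4 at 2.28 and Tnfrsf18 at 1.97, which were −1.09 and −1.81 within the batch. Monocyte and macrophage markers fell (17 of 19 negative, −1.35, adjusted p = 2.4e-05), with Spp1 at −3.28 and Cd14 at −2.49, as did dendritic cell markers (4 of 4, −2.38, 0.00281) and mitochondrially encoded transcripts (7 of 10, −2.44, 0.0217). The mitochondrial list includes mt-Co2, mt-Co3 and mt-Atp6, which had 0 reads in anti-PD-1 replicates 1 and 2. Within the batch its median was −1.25, with 10 of 10 members negative. With an estimated correlation the adjusted p of each of the 7 was 0.585, and by fry 0.508. Members that passed over all genes numbered 0. Adjusted over the list alone, 3 of the dendritic cell markers passed, 3 of the homing genes (Cx3cr1 −1.90, Cxcr6 3.82 and Itgal 3.13) and 1 of the inhibitory receptor genes (Id2).

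These calls moved with the libraries that lack Cd3e. Within the batch the medians were 0.31 for interferon-gamma-induced genes, 0.06 for activation, 0.13 for glycolysis, −1.24 for regulatory T cell genes and −0.41 for macrophage markers. Without the pair, the anti-PD-1 group is replicate 3 alone, assumed to vary like the D18 libraries, so a p-value then rests on 1 library. In that comparison 3 lists passed, all down, among them regulatory T cell genes (adjusted p = 0.00598), which had been up, while interferon-gamma-induced genes had an adjusted p of 0.148, activation 0.851, glycolysis 0.409, macrophage markers 0.182 and dendritic cell markers 0.0692. With batch as a term, which rests on the same library, 3 passed, all down (type I interferon-stimulated genes, regulatory T cell genes and mitochondrial transcripts, each with an adjusted p of 0.0412), and the adjusted p of the macrophage markers was 0.216. Without D18 replicate 2 only 2 lists passed, the macrophage and dendritic cell markers. The others then had adjusted p of 0.123 (interferon-gamma-induced), 0.123 (activation), 0.125 (glycolysis), 0.251 (regulatory T cell) and 0.218 (mitochondrial). The regulatory T cell list was also lost without anti-PD-1 replicate 1 (adjusted p = 0.322) or 2 (0.0860), and glycolysis without anti-PD-1 replicate 2 (0.405). Mitochondrial transcripts were lost without anti-PD-1 replicate 2 (adjusted p = 0.0860) or 3 (0.0669) and with the replicate block (0.0539). Type I interferon-stimulated genes passed, down, without anti-PD-1 replicate 2 (adjusted p = 0.0145). Without anti-PD-1 replicate 3, cytotoxic effector genes (adjusted p = 0.0185) and inhibitory receptor genes (0.0226) passed, up.

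Other lists in the CD4+ T cell sort did not pass. Cytotoxic effector genes had a median of 1.94 (4 of 6 higher, −0.53 within the batch, adjusted p = 0.0916, but 0.0263 by camera with the replicate block), with Gzmb at 0, 11 and 81 reads against 52, 31 and 157 (3.03 ± 1.26, and 0.46 within the batch). Inhibitory receptor genes had a median of 1.14 (5 of 5, −1.35 within the batch, adjusted p = 0.0916). Pdcd1 among them had 2, 1 and 45 reads against 20, 2 and 19 (1.14 ± 1.37, and −1.35 within the batch). Medians were 1.32 for Th1 genes (−0.54 within the batch, adjusted p = 0.325), 0.12 for homing (0.513), 0.84 for hypoxia response (0.256), 0.00 for oxidative phosphorylation (0.621) and −0.44 for the unfolded protein response (0.176). MHC class I presentation (0.49, adjusted p = 0.150), sample-handling stress (−0.16, 0.584) and type I interferon-stimulated genes (−0.05, 0.584) complete them, and with an estimated correlation the smallest adjusted p of all these lists was 0.585. Too few members were measured to test naive and memory genes (2 members, Ltb at 3.05 and Il7r at 0.99, within the batch −0.02 and −0.65), Th2 genes (1, Plac8 at 0.65), Th17 genes (1, Tmem176b at −1.68), follicular helper genes (2, Icos and Pdcd1) and cell cycle genes (1, Pcna at 0.34). Foxp3, the lineage factor of regulatory T cells, had 0, 0 and 30 reads with anti-PD-1 and 3, 4 and 5 with D18. Ifng had 0, 0 and 3 against 12, 2 and 40, and both were too low to test, like Prf1, Tnf, Havcr2, Tcf7 and Mki67.

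In the dendritic cell sort the median log2 change of all 886 tested genes was −0.65, so changes in this sort are given relative to that median unless said otherwise. In D18 replicate 2, with 11170 reads, 1 read is 4.81 normalised reads. Without that library and anti-PD-1 replicate 2, a change and its relative value hardly differed (Il7r, 2.13 and 2.12). The shift thus rests on these libraries, and a relative change above 0 need not be a rise. Spp1, which encodes the secreted phosphoprotein osteopontin, had 277, 195 and 373 reads with anti-PD-1 and 55, 0 and 69 with D18 (relative log2 change −3.79 ± 1.30, SE, n = 3 per group, ENSMUSG00000029304.14, chromosome 5, 104435118 to 104441050). Rgs1, a regulator of G protein signalling (−1.69), Cd72 (−1.60), Lgmn (−1.64) and Sat1 (−1.48) also kept the groups apart. Higher with D18 were Lars2 (3.63), mt-Co3 (4.76), Malat1 (3.05), AA467197 (2.36) and the ribosomal protein genes Rps27 (2.51) and Rpl37a (2.72). Within the batch, the changes of mt-Co3, Rps27 and Rpl37a, not relative, were 0.88, 0.41 and 0.22, and that of Spp1 was −4.13. By limma 0 genes passed, with a smallest adjusted p of 0.551. An unadjusted p under 0.05 was found for 61 (19 higher, 42 lower), limma-voom called 0, and with batch as a term limma called 0 with 0 at an unadjusted p under 0.05. The groups did not overlap for 24.0% of the genes, against 10% by chance.

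Without dendritic cell anti-PD-1 replicate 2, with 71.9% mitochondrial reads, and D18 replicate 2, with 11170 reads, 11 genes passed. Il7r, AW112010, Gsn and Tmem119 among them were chosen after their values were seen. Gbp2, an interferon-induced GTPase (3.08), Il1rn, the interleukin-1 receptor antagonist (3.02), AW112010 (2.14), Il7r (2.12) and Lars2 (1.99) were higher. Spp1 (−2.83, adjusted p = 0.00657), Tmem119 (−2.31), Gsn (−2.01), the fractalkine receptor gene Cx3cr1 (−1.98) and Rgs1 (−1.93) were lower.

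By camera 3 of 16 lists passed in this sort. Inflammatory cytokines, chemokines and NF-kappaB targets rose as a list (5 of 8 members positive before the median of all genes was taken off, relative median 1.29, adjusted p = 0.0361). Among them Tnfaip2 had 3, 0 and 2 reads against 22, 11 and 11 (3.67), and Il1rn 3, 7 and 8 against 124, 1 and 39 (2.50). Markers of conventional type 2 dendritic cells fell (6 of 6 negative before the median was taken off, relative median −0.68, adjusted p = 0.0493), with Cx3cr1 (−2.26), Clec4a2 (−2.22) and the growth factor receptor Csf1r (−0.87), and both Cx3cr1 and Csf1r are genes of macrophages too. Mitochondrially encoded transcripts passed as higher relative to the other genes (6 of 10 positive and a median of 0.07 before the median of all genes was taken off, relative median 0.72, adjusted p = 0.0361), and mt-Co2, mt-Co3 and mt-Atp6, without a read in anti-PD-1 replicates 1 and 2, are among them. With an estimated correlation the adjusted p of all 3 was 0.771. In the same order, by fry it was 0.710, 0.321 and 0.853, and with batch as a term the adjusted p was 0.0607, 0.125 and 0.246. No member passed over all genes or adjusted over the list alone. Without D18 replicate 1, 0 lists passed (adjusted p = 0.0571 for all 3), and without anti-PD-1 replicate 1 only the inflammatory list did. The inflammatory list was lost without anti-PD-1 replicate 2 (adjusted p = 0.0638). The type 2 list was lost without anti-PD-1 replicate 1 (adjusted p = 0.163) or 3 (0.0581) or D18 replicate 3 (0.221). The mitochondrial list was lost without D18 replicate 2 (adjusted p = 0.203) and turned down without anti-PD-1 replicate 1 (0.672). Interferon-gamma-induced genes passed, up, without anti-PD-1 replicate 2 (adjusted p = 0.0390) or D18 replicate 2 (0.0230). MHC class II genes passed, down, without anti-PD-1 replicate 3 (adjusted p = 0.0320) and macrophage markers without D18 replicate 2 (0.0278).

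Lists central to antigen presentation did not pass in dendritic cells. All 11 tested MHC class II genes were lower before the median was taken off, with a relative median of −0.64 (adjusted p = 0.0565, and adjusted p = 0.771 with an estimated correlation). H2-Aa had 151, 689 and 269 reads against 391, 11 and 289 (relative −0.43 ± 0.94), and its change turned to 0.26, not relative, without anti-PD-1 replicate 2 and D18 replicate 2. Maturation genes were mostly too low for a test. Cd86, a ligand of CD28, had 7, 19 and 26 reads against 18, 3 and 21 (0.53), Cd40 at most 5 in a library, Ccr7 at most 8, Cd80 1 in all 6 and Il12b 0 in all 6. Cxcl9, a chemokine that draws T cells, had 1, 0 and 2 reads with anti-PD-1 and 13, 8 and 24 with D18 and lay below the level needed for a test. Cxcl10, of the same family, had 31, 5 and 28 against 67, 1 and 35 (0.77). Not relative to the median, the changes of Cd86 and Cxcl10 turned their signs with quantile normalisation, to 0.01 and −0.05. Cd274, Isg15 and Xcr1 were also too low.

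Interferon-gamma-induced genes in dendritic cells had a relative median of 0.77 (5 of 9 positive before the median was taken off, adjusted p = 0.0565), with Gbp2 at 2.51 and Gbp7 at 2.71, and type I interferon-stimulated genes −0.17 (adjusted p = 0.419), with Usp18 at −1.88. The unfolded protein response (−0.52, adjusted p = 0.0690), Toll-like receptors (−0.27, 0.325), glycolysis (−0.20, 0.325), hypoxia response (−0.11, 0.419), MHC class I (−0.13, 0.614) and sample-handling stress (0.03, 0.863) did not pass. Nor did type 1 dendritic cell markers (1.07, adjusted p = 0.419) or oxidative phosphorylation (0.67, 0.189), whose median of 0.02 and mean of −0.21 before the median of all genes was taken off differ in sign. Of other cells, monocyte and macrophage markers had a relative median of −0.58 (adjusted p = 0.0565) and T cell markers 1.31 (0.321), the latter −2.73 within the batch, not relative. With an estimated correlation the smallest adjusted p of all these lists was 0.771. Plasmacytoid markers (1 member, Lair1 at −1.72), cell cycle genes (1, Pcna at 0.85) and maturation genes (2 members) were too few to test.

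**Figure D4:**
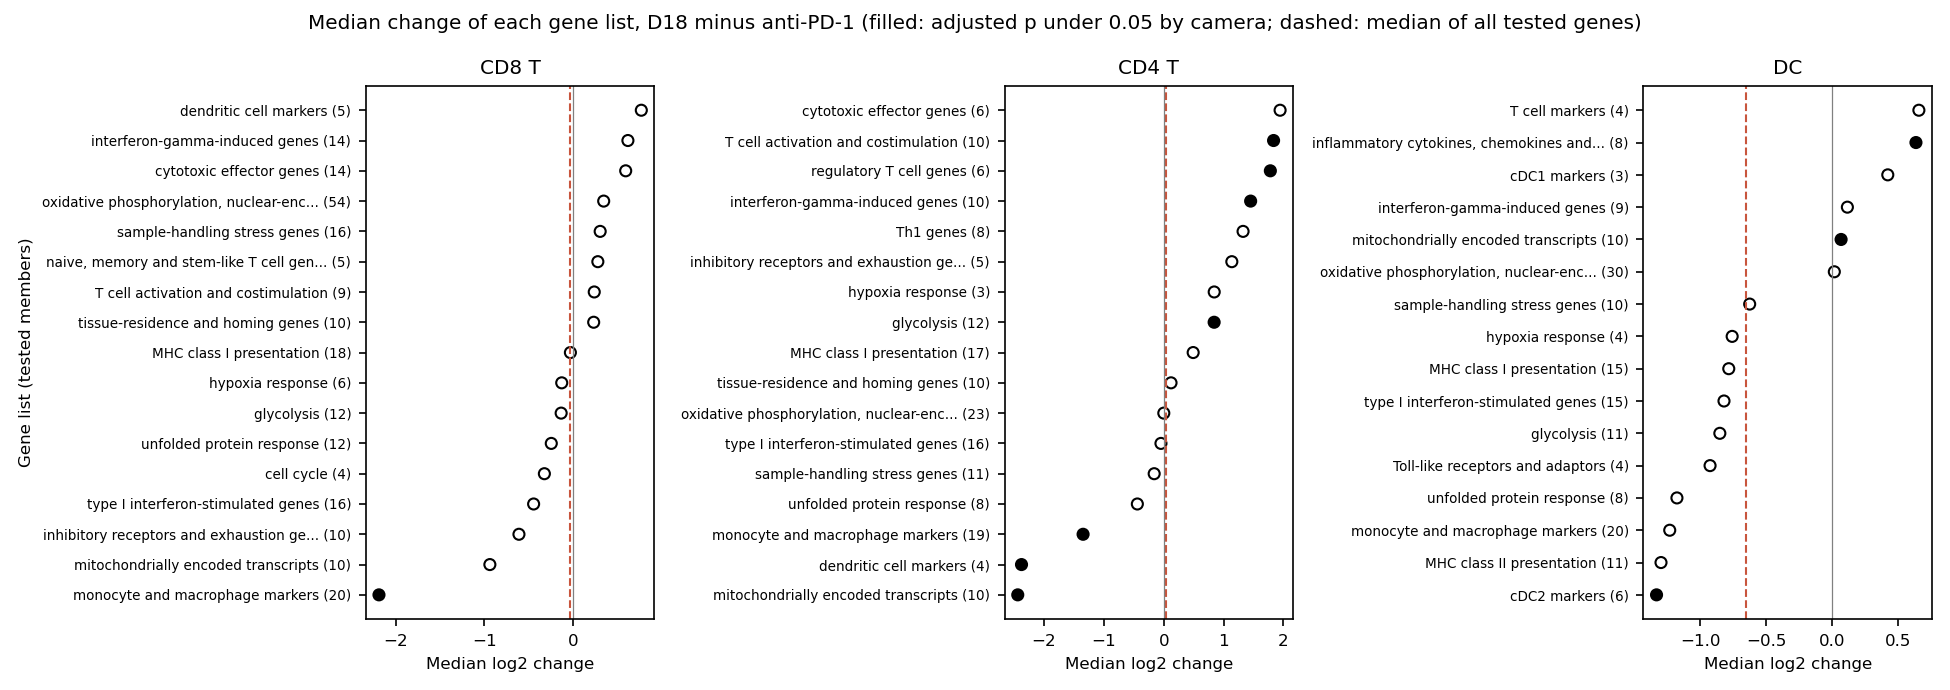
Points give the median log2 change (D18 minus anti-PD-1) of the tested members of each gene list in the 3 sorts, with their number in brackets; filled points passed camera with the preset correlation, the dashed line is the median of all tested genes. In the CD8+ T cell sort 1 list passed, in the CD4+ T cell sort 7 and in the dendritic cell sort 3.

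Whether the changes with D18 differed between the 3 sorts was tested as an interaction. Cd69, an early activation marker, was at 0.24 in CD8+ and 2.21 in CD4+ T cells (difference −1.96 ± 0.82, SE), and Tnfaip8, a regulator of cell death, gave the smallest p of that pair (−2.94 ± 1.15). Usp18, a brake on interferon signalling, gave differences of 2.95 ± 1.23 between CD8+ T cells and dendritic cells and of 3.19 ± 1.23 between CD4+ T cells and dendritic cells. Marcks, a substrate of protein kinase C, gave −2.85 ± 1.04 for the last pair. The dendritic cell changes behind these differences are not relative to their median of −0.65. In the CD4+ T cell sort, anti-PD-1 replicates 1 and 2 held 0 and 1 reads of Cd3e. Its changes, that of Cd69 included, therefore cannot be told from a difference in cell content. Libraries numbered 3 of different sorts, taken as independent here, correlated at 0.84 to 0.95. None of these differences passed. limma called 0 of 916 genes for CD8+ against CD4+ T cells, 0 of 816 for CD8+ T cells against dendritic cells and 0 of 744 for CD4+ T cells against dendritic cells. The smallest adjusted p were 0.995, 0.985 and 0.750, with 6, 7 and 22 genes at an unadjusted p under 0.05. Without both libraries numbered 3, again with batch and treatment coinciding, 1 gene passed between CD4+ T cells and dendritic cells, Ms4a4b (7.27, adjusted p = 0.0242). Within the 12 libraries of 1 batch 0 genes passed by limma in any of the 3 pairs, with 0 at an unadjusted p under 0.05. With all 18 libraries, no gene tested in both cell types of a pair was therefore shown to differ in its change. Gene lists, and genes tested in only 1 sort, were not part of this test.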

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

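All tests here were chosen after the patterns had been seen. The prediction for sequencing depth was written before its test was run, and all others after the values they concern had been seen.

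Apoe and 18 other members of the monocyte and macrophage list were lower with D18 in the CD8+ T cell sort (median −2.19). Less macrophage RNA in the sorted cells would lower the abundant members by a single factor, and after the median member was taken off 3 of 10 abundant members still kept the groups apart, Apoe (−2.35), C1qb (−0.46) and Ly6c2 (3.53), so this test cannot tell. Deeper anti-PD-1 libraries were excluded, since thinning every library to 55823 reads left a median of −1.86 ± 0.095 (SD over 20 drawings). The library batch shared by anti-PD-1 replicates 1 and 2 cannot be told from treatment, because the median of −3.12 within the other batch rests on 1 anti-PD-1 library. Among the other splits of the same 6 libraries, 3 gave a smaller adjusted p for this list by camera (1.8e-07, 3.3e-09 and 1.4e-12), each with D18 replicates 1 and 2 on the same side.

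Gzma had no read in the anti-PD-1 libraries of the CD8+ T cell sort. Too few reads in these libraries were excluded, since at the lowest rate with D18 (305 CPM) they would hold 125 reads. Natural killer cells in the sort with D18 stay open as a source: their list took 102 reads of 411387 with anti-PD-1 and 78 of 400208 with D18, a ratio of 0.786, but 1.96 without anti-PD-1 replicate 2, and the 95% interval over libraries (0.185 to 4.41) is too wide to decide. The anti-PD-1 libraries numbered 3 lie in the batch of the D18 libraries. At the lowest ratio to Cd8a with D18 they would hold 38.4 reads (13.2, 4.40 and 20.8 in the 3 sorts), and they held 0. These 3 libraries resemble each other (correlations of 0.84 to 0.94) and may hold the same material. The test therefore cannot decide on the library batch of replicates 1 and 2, which stays open. Gzma had 38 and 44 reads in CD4+ T cell and dendritic cell D18 replicate 3.

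mt-Co2, mt-Co3 and mt-Atp6 had no read in anti-PD-1 replicates 1 and 2 of any sort. Too few mitochondrial reads in the 6 libraries were excluded, since at the lowest ratio to mt-Cytb they would hold 2404 reads of the 3 genes. Reads shared with near-identical copies may have been kept or dropped differently between library batches. The test fits this: the highest pseudogene share in the 6 libraries, 0.507% of nuclear reads, lies under the lowest in the other 12, 0.694%. The pseudogenes Gm10925 and Gm28437 together had 12 reads in the 6 libraries and 1291 in the 12.

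Counts of passing genes were set against other splits of the libraries, a test chosen after the counts were seen. In each cell type 10 of 10 splits gave at least the real 0 genes, as any count must, and no other split gave any. With the replicate block 1 of 4 splits within pairs, the real one, gave 20 genes, and the others 0, too few splits for a share under 0.05. For lists, 10 of 10 splits gave at least the real 1 in CD8+ T cells (highest 5), 3 of 10 at least the real 7 in CD4+ T cells (highest 9) and 3 of 10 at least the real 3 in dendritic cells (highest 4), with too few splits for a share under 0.05. The CD4+ T cell splits with 9 and 8 lists and the dendritic cell split with 4 keep anti-PD-1 replicates 1 and 2, which share a batch, on the same side, and with batch as a term 3 and 0 lists passed in these sorts. For interactions 100 of 100 splits gave at least the real 0 genes, as any count must. Of the other splits 3, 2 and 4 called any gene in the 3 pairs of cell types, with highest counts of 8, 4 and 17.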

How the results depend on the processing

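Settings called added, and the choice of values given here, came after the results were seen, and the cause of a moved result was not tested unless named. Depth limits all of them, since 3 reads are up to 269 CPM. Median-ratio size factors were not tried against others, since the deposited values already carry them. The planned negative-binomial tests were not run, although whole reads could be recovered, since the deposited unit is log2, so how many genes they would call is not known. Of 650 alternative list values, 554 stayed on their side of the threshold (37 of them with a turned sign, neither passing), 63 lost the call, 29 gained it and 4 reversed. Of 1246 values of 59 named genes, 1094 stayed on their side (16 of them with a turned sign), 152 gained a call and 0 reversed. Genes (0 in each sort) numbered 22 in CD8+ and 29 in CD4+ T cells with no filter, where the trend is fitted to many genes near 0 reads. In CD8+ T cells the replicate block gave 20 genes, with quantile normalisation 6, pseudocount 10 57, deposited log2 values 41, voom and quality weights 37, and without pair 1, 2 or 3 15, 28 and 1. One fit of all 18 libraries gave 1 (Trbv17, −4.55), and the deposited log2 values as they stand 1. Leaving out each library gave 0 to 2 genes in CD8+ T cells and 0 to 19 in CD4+ T cells. Without both libraries numbered 3 (added), where batch and treatment coincide, CD4+ T cells gave 34 genes and the difference between CD4+ T cells and dendritic cells 1. Without libraries over 50% mitochondrial or under 20000 reads (added), dendritic cells gave 11 and CD4+ T cells 0. Lists (1, 7 and 3) fell to 0 in each sort with an estimated correlation and to 0 with fry. The block gave 2 in CD8+ T cells, and quantile normalisation 1 in dendritic cells. Leaving out each library gave 2 to 3 lists in CD8+ T cells, 2 to 8 in CD4+ T cells and 0 to 4 in dendritic cells. Without both libraries numbered 3, CD8+ T cells gave 3. The pair with at most 1 Cd3e read left out gave 3 in CD4+ T cells, and the batch term (added) 7, 3 and 0. Reversed were dendritic cell markers in CD8+ T cells with the batch term (adjusted p = 0.0355), regulatory T cell genes in CD4+ T cells without that pair (0.00598) and with the batch term (0.0412), all 3 resting on a single anti-PD-1 library assumed to vary like the others, and mitochondrial transcripts in dendritic cells without anti-PD-1 replicate 1 (0.672, against 5.2e-07 in the first direction without replicate 2).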

Other observations

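The cross-sort values here were computed after the results above had been seen. B cell genes appeared in the dendritic cell sort. Dendritic cell D18 replicate 1 held 265 reads of the B cell list and the other D18 libraries 1 and 96, against 9, 8 and 18 with anti-PD-1. In CPM these were 1390, 89.5 and 567 with D18 against 151, 36.0 and 105. D18 replicate 3 of the CD8+ and CD4+ T cell sorts held 474 and 765 CPM, so the value of replicate 3 was not particular to this sort. Among the 265 were 65 of the immunoglobulin light chain gene Igkc, 58 of Cd79b and 34 of Cd79a, both parts of the B cell receptor, and 18 of Fcrla. Flt3, the receptor of a growth factor that dendritic cells depend on, had 0 reads in the 3 anti-PD-1 libraries of that sort and 13, 1 and 3 with D18, and the dendritic cell integrin gene Itgax had 20, 17 and 22 against 52, 3 and 38.

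Effector genes of cytotoxic cells were found in the CD4+ T cell sort. Nkg7, a granule protein of cytotoxic cells, had 1, 1 and 150 reads with anti-PD-1 and 37, 12 and 225 with D18, and Ctsw, a cysteine protease of the same cells, 0, 0 and 22 against 35, 2 and 69. The libraries numbered 3, with the most Nkg7 reads, also held 15 (anti-PD-1) and 83 (D18) reads of Cd8a, while D18 replicate 1 held 0. Whether CD8+ T cells in the libraries numbered 3 were the source was not tested. Ccl5, a chemokine of activated T cells, had 0, 0 and 62 reads against 7, 0 and 160 in the dendritic cell sort. Libraries numbered 3 of different sorts were alike across 1518 genes, with correlations of 0.84 to 0.95, where those of replicates 1 and 2 lay between 0.12 and 0.79.

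The log2 changes with D18 correlated across genes between sorts, and genes are not independent replicates. The correlation was 0.53 between CD8+ and CD4+ T cells, 0.56 between CD8+ T cells and dendritic cells and 0.39 between CD4+ T cells and dendritic cells. Without the libraries numbered 3 it was 0.45, 0.43 and 0.25, from libraries in which batch and treatment coincide in every sort. Without mitochondrial, ribosomal and pseudogene transcripts it was 0.51, 0.50 and 0.39. Among 100 splits of the libraries, real one included, 5, 1 and 18 of the others gave a correlation as large in either direction, and the largest were 0.58, 0.65 and 0.66 in size.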
